A study of Mus musculus with 6 samples.

How the data were processed

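Liver total RNA of 6 male mice aged 8 weeks was extracted with TRIzol, labelled with biotin and hybridised to 1 Affymetrix array per mouse, per the labels. The labels put 3 arrays in the HFD-inulin group (offspring of mothers given inulin, titled HFD-inulin) and 3 in the HFD group (offspring of high-fat diet mothers). The labels do not say whether the 3 mice of a group came from separate mothers or litters, so p-values measure the spread between these samples, part of which may be shared or technical. The values used are the authors' deposited log2 signals, 1 column per array, for 65956 probe sets. They were made with Affymetrix Expression Console 1.0, per the submitters' processing notes. The summarization algorithm, the background correction, the genome build and any filter are not given in the sources used here. The log base was read from the values, which run from about 0 to about 12 in each array. The array medians were 1.20, 1.17 and 1.25 in HFD-inulin arrays 1 to 3 and 1.20, 1.25 and 1.26 in HFD arrays 1 to 3, so the values were not centred on 0. Scanner files and detection calls were not used here, so no slide or scan batch was tested and no probe set has a stated limit of detection. Low log2 values near the array median carry little signal over background.

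Probe sets were named through the platform annotation of GEO, which lists a symbol for 32750 of them, and older symbols were updated through a RefSeq gene table (assembly GRCm38.p6). This named 31258 probe sets with 1 gene (30702 distinct genes), left 1492 with several genes unnamed, and left 33206 with no listed symbol unnamed. Of the named probe sets, 1152 had their symbol updated and 2 had no match in the RefSeq table. The array's build is not named, so no coordinates are given. The probe set number lies on another chromosome than the gene for 102 named probe sets, and these were left out as an alternative. A probe set counted as noncoding where RefSeq types its gene as a noncoding RNA that is not a pseudogene, which gave 6519 probe sets, 3425 of them lncRNA. Probe sets with no name were not typed.

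The groups were compared as HFD-inulin minus HFD with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the deposited log2 values of all 6 arrays, with no filter and no covariate, two-sided, with Benjamini-Hochberg adjustment over all 65956 probe sets and a threshold of 0.05. Gene lists were tested with limma's camera (preset correlation 0.01) on 1 probe set per gene, the one with the highest mean over the 6 arrays, with Benjamini-Hochberg adjustment over 39 lists. Per-array list means are means over the list's genes of the log2 signal minus the HFD group mean. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule names, among genes that are neither noncoding nor predicted models, up to 10 higher and 10 lower with adjusted p under 0.05 and groups that do not overlap. Free places go to the lowest unadjusted p under 0.05 with a fold of at least 1.5, a mean at or above the median probe set (1.22) and groups that do not overlap. It names up to 5 noncoding probe sets each way by the same criteria, 18 anchor genes of lipid, bile acid and glucose metabolism whatever their values, and up to 4 members of each list described, those with the smallest unadjusted p. No probe set passed the adjusted threshold, so every place was filled by unadjusted p. Of the anchor genes, 14 were measured under a single name, and the others are not reported here.

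Before use, the fits were tested on simulated data for HFD-inulin against HFD. Of 50 probe sets planted at each size among 65956, limma recovered 22 at a log2 change of 0.585, 35 at 1, 45 at 2 and 48 at 3, with 9 calls among unchanged probe sets. On 30702 genes camera called 3 of 3 shifted lists and 0 of 37 others, with a preset and with an estimated correlation. The simulated noise was independent between genes, which real arrays need not have.

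Of all probe sets, 1633 share their 6 values exactly with another, and 245 of these are numbered on chromosome Y. They are called many-copy probe sets here, from their identical values alone, since probe sequences were not checked. The mean of those on chromosome Y defined a split of the arrays that crosses the groups. The split was found after the data were examined, and its cause is not known. The comparison was then repeated with the split as a block, within each of its parts, with HFD-inulin array 3 alone against HFD, without probe sets that share a profile, and without those numbered on another chromosome. Settings chosen before the data were examined were another variance prior, a filter on dim probe sets, quantile normalization, median centring, array weights, the replicate number as a block, each array left out in turn, other thresholds, ordinary least squares, other set tests and other choices of probe set. Nothing in the labels pairs the animals, so the replicate numbers were not read as pairs. Deviations from the group means correlated at 0.261, -0.278 and 0.404 between arrays of the same number (Pearson r across probe sets). Between arrays of different number they ran from -0.543 to 0.423. With 3 arrays per group these values cannot decide on pairing. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the figures.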

Results

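The study profiled the livers of 8-week-old male mice on arrays that carry probe sets for protein-coding genes and noncoding RNAs. Inulin is a fermentable plant fibre. The mothers of 3 mice had received it, in a group titled HFD-inulin, and those of the other 3 a high-fat diet (HFD). Since the first title also names HFD, the comparison is not read here as inulin in place of a high-fat diet. The design asks which hepatic transcripts, noncoding RNAs in particular, differ between the offspring of these mothers. The number of arrays, 3 per group, limits the precision of every value below.

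The arrays did not separate by group in their main component. The first principal component held 53.1% of the variance and set HFD-inulin array 3, HFD array 2 and HFD array 3 apart from HFD-inulin arrays 1 and 2 and HFD array 1. Chromosome Y probe sets with a shared profile split the arrays the same way. Their mean log2 signal was 1.91, 1.60 and 3.15 in HFD-inulin arrays 1 to 3 and 1.34, 3.24 and 2.99 in HFD arrays 1 to 3. HFD-inulin array 3 correlated more closely with HFD arrays 2 and 3 (Pearson r across probe sets 0.9948 and 0.9949) than with HFD-inulin arrays 1 and 2 (0.9878 and 0.9828). HFD array 1 in turn correlated more closely with HFD-inulin arrays 1 and 2 (0.9913 and 0.9889) than with HFD arrays 2 and 3 (0.9835 and 0.9855). Below, "low-signal arrays" are HFD-inulin 1 and 2 with HFD 1, and "high-signal arrays" are HFD-inulin 3 with HFD 2 and 3.

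**Figure D1:**
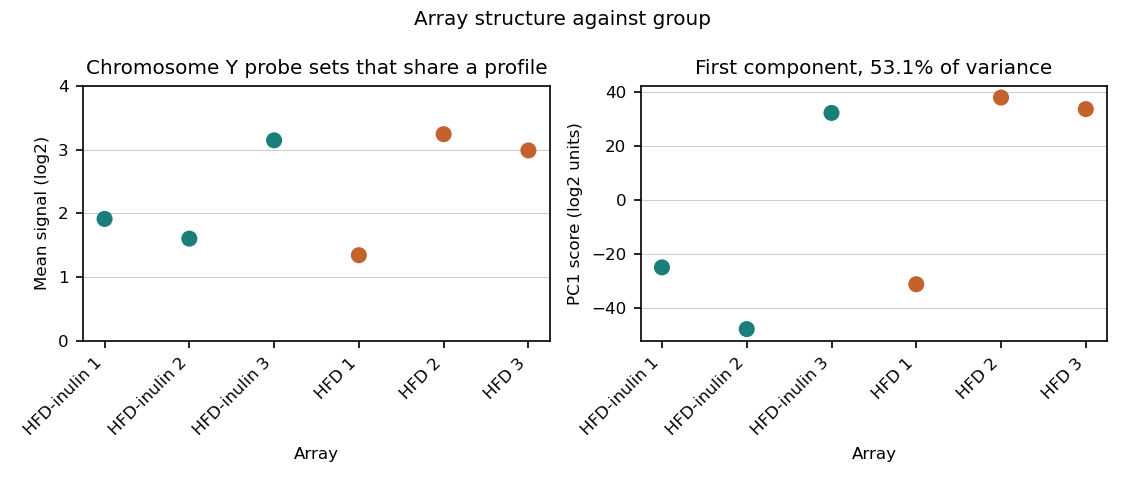
Mean log2 signal of the 245 chromosome Y probe sets that share a profile (left) and score on the first principal component (right), 1 point per array, HFD-inulin in green and HFD in orange. In both panels HFD-inulin 3 lies with HFD 2 and HFD 3, and HFD 1 lies with HFD-inulin 1 and 2.

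No probe set passed the adjusted threshold, and the genes named here were taken by unadjusted p among those whose groups did not overlap. Hnf4a, Foxo3 and Nr1d1 had the smallest p among the 20 and were lower in the HFD-inulin livers. Hnf4a, a nuclear receptor that maintains hepatocyte gene expression, measured 6.83 ± 0.05 (SD, n = 3) in HFD-inulin and 7.43 ± 0.04 in HFD, a log2 difference of -0.60. Foxo3, a forkhead factor restrained by insulin signalling, measured 3.82 ± 0.02 against 4.41 ± 0.05, a difference of -0.59. Nr1d1, which encodes the clock repressor REV-ERB alpha, measured 4.64 ± 0.20 against 5.70 ± 0.09, a difference of -1.06. Their adjusted p in limma was 0.390 for each. Bcl6, a transcriptional repressor with male-biased expression in mouse liver, had the largest difference of the 10 lower genes named, -1.62 (SE 0.31, limma adjusted p = 0.902). Onecut1, a hepatic homeodomain factor also called HNF6, was the largest of the 10 higher ones, with 5.29 ± 0.69 against 3.77 ± 0.43 and a 2.87-fold ratio (limma adjusted p = 0.902).

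The other lower genes named were Gldc, the glycine decarboxylase of the glycine cleavage system (-0.82, SE 0.10), Elovl2, an elongase of polyunsaturated fatty acids (-0.85), Fam214a (-0.97), Plekhf1 (-0.62), Rcan1, a regulator of calcineurin (-0.59), and Zfp36, which promotes decay of AU-rich mRNAs (-0.72). The other higher ones were Dipk2a (1.07, SE 0.27), Osgin1, an oxidative stress responsive gene (0.71), Msmo1, a methylsterol oxidase of cholesterol synthesis (0.59), Blvrb, biliverdin reductase B (0.60), and Timm8a1, a mitochondrial import protein (0.63). The rest were Rpl35 (0.63) and the ribosomal protein pseudogenes Rpl38-ps1 (0.73), Rpl30-ps11 (0.67) and Rpl15-ps6 (0.61). Processed pseudogenes resemble the mRNA of their parent genes, and the probes were not checked for sharing here. The probe sets named for Timm8a1 and Rpl35 are numbered on another chromosome than the gene. The other probe set of each gene gave 0.44 for Timm8a1 and 0.59 for Rpl35. The adjusted p of each gene in this paragraph was 0.902 in limma. All 21 genes the rule named outside the anchors had the same sign of difference in the low-signal and in the high-signal arrays. This was fixed by the rule, which admits only genes whose groups do not overlap. The sizes could differ. In the low-signal and high-signal arrays they were -0.52 and -0.68 for Hnf4a, -1.07 and -0.93 for Nr1d1, and -2.27 and -0.83 for Bcl6.

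**Figure D2:**
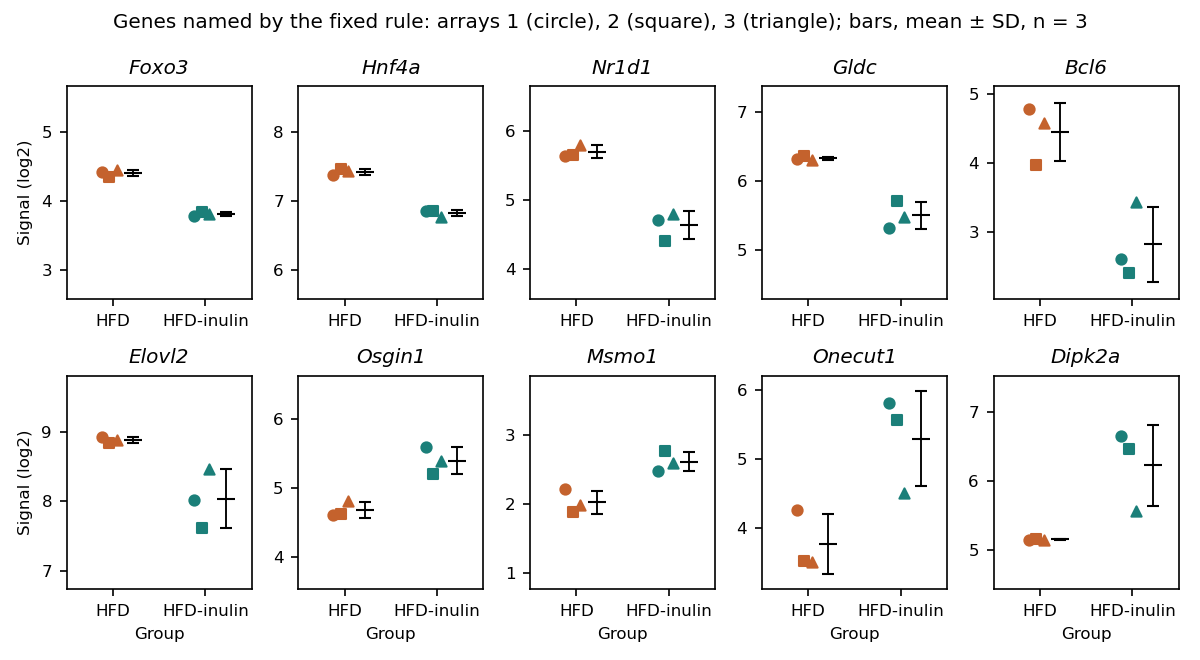
Log2 signal of 10 named genes per array (circle, square and triangle for arrays 1, 2 and 3), with the group mean ± SD (n = 3) beside the points; every panel spans the same height on the log2 axis. Groups do not overlap in any panel, and the HFD-inulin points of Onecut1 and Dipk2a spread more widely (SD 0.69 and 0.58) than those of Foxo3 and Hnf4a (SD 0.02 and 0.05).

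Over all 65956 probe sets, 0 passed an adjusted p of 0.05 in limma. At an unadjusted p under 0.05 there were 3399 (1660 higher and 1739 lower), or 5.15% of those tested. That count was 6525 without HFD-inulin array 3, 2100 without HFD array 2 and 2218 without HFD array 3. The groups did not overlap in 10.3% of probe sets, where chance gives 10%. Ordinary least squares also called 0, and limma with a trended and robust prior called 4. Those 4 probe sets share an identical profile and have no gene name here. One of them, TC1000001422.mm.1, measured 2.35 ± 0.05 in HFD-inulin and 3.46 ± 0.12 in HFD (n = 3), a difference of -1.11. Its adjusted p of 0.0742 in limma was the smallest of the comparison. The adjustment counted this 1 profile 4 times, which lowers its adjusted p. With the many-copy split as a block limma again called 0, with a smallest adjusted p of 0.114, and within the low-signal arrays and within the high-signal arrays it called 0.

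The design asks in particular about noncoding RNAs, and none passed the test. Of 6519 noncoding probe sets 0 passed in limma, whether adjusted over all probe sets or adjusted over the list alone (smallest adjusted p 0.902 and 0.947). Without adjustment 187 lay under 0.05, 51 higher and 136 lower, and this count was 391 without HFD-inulin array 1, 299 without HFD-inulin array 3 and 434 without HFD array 1. Of the 3425 lncRNA probe sets, 91 did, 16 higher and 75 lower. These are 2.87% of noncoding and 2.66% of lncRNA probe sets, below the 5.15% of all probe sets, so the counts show no excess. The median difference was -0.027 over lncRNA probe sets and -0.016 over all probe sets. The rule named 1 noncoding gene, the lncRNA Gm12909, at 2.31 ± 0.27 in HFD-inulin and 2.91 ± 0.13 in HFD (SD, n = 3). Its difference was -0.60 in all 6 arrays, -0.61 in the low-signal and -0.35 in the high-signal arrays (limma adjusted p = 0.902). The other 4 noncoding probe sets with an unadjusted p under 0.05 and a fold of at least 1.5 were higher and overlapped between groups. They are the small nucleolar RNAs Gm24613 (0.64), Gm26048 (0.85), Gm25370 (0.76) and Gm26493 (0.76), named after their values were seen. The list of 30 named long noncoding RNAs had a median difference of -0.02 and was not called (camera adjusted p = 0.954). Its members with the smallest p were Snhg18 (0.31), Peg13 (-0.29), Rmrp (0.47) and Gm15441 (2.04, SE 0.91).

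The gene lists gave 18 calls of 39 with camera, 6 higher and 12 lower in HFD-inulin. With an estimated correlation 0 of 39 were called, and fry called 1, adipose markers. The preset of 0.01 treats a list's genes as nearly independent, while the estimate reached 0.822, for acute phase genes. No list member passed limma's threshold adjusted over all probe sets. Adjusted over the list alone, 1 member passed in each of the lists of cholesterol synthesis (Msmo1), insulin signalling (Foxo3), xenobiotic metabolism (Sult5a1), male-biased genes (Bcl6), circadian clock (Nr1d1) and hepatocyte markers (Hnf4a), and 2 in the immediate early genes (Zfp36 and Ier3). In the other 32 lists 0 passed. With the many-copy split as a block camera called 17 lists, 16 of them among the 18. Within the low-signal arrays (HFD-inulin 1 and 2 against HFD 1) 16 of the 18 kept their call and direction, and within the high-signal arrays (HFD-inulin 3 against HFD 2 and 3) 2 did, cytosolic ribosomal proteins and periportal genes. Each of these parts has a group with a single array, which is assumed to vary like the others.

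Cytosolic ribosomal protein genes had the smallest p. All 21 measured members were higher in HFD-inulin, with a median log2 difference of 0.30, and in 14 the groups did not overlap. Chance gives 10% for 1 gene, but the members moved together (estimated correlation 0.786), so the 14 are not separate observations. The exact permutation p of the list mean was 0.1, the smallest possible. The periportal, bile acid and adipose lists reached that value too, as did the uncalled hepatocyte, one-carbon and lipoprotein lists. In the other called lists the exact permutation p ran from 0.2 to 0.5. For the ribosomal list the camera adjusted p was 1.25e-15, and 0.581 with an estimated correlation. The list mean was 0.33, 0.51 and 0.12 above the HFD mean in HFD-inulin arrays 1 to 3 and 0.06, -0.08 and 0.02 in HFD arrays 1 to 3. The difference was 0.36 in the low-signal and 0.15 in the high-signal arrays, and the adjusted p with the split as a block was 1.19e-14. Members with the smallest p were Rpl27 (0.47), Rpl35 (0.63), Rpl22 (0.26) and Rpl8 (0.43), of which Rpl27 and Rpl35 are measured by probe sets numbered on another chromosome.

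Genes of cholesterol synthesis were also higher, 17 of 19, with a median of 0.17 (camera adjusted p = 0.000324, and 0.581 with an estimated correlation). Msmo1 (0.59), the lanosterol demethylase gene Cyp51 (0.54), the lanosterol synthase gene Lss (0.35) and the sterol-sensing transcription factor gene Srebf2 (0.21) had the smallest p. The list mean was 0.35, 0.23 and 0.07 in HFD-inulin arrays 1 to 3. In HFD arrays 1 to 3 it was 0.12, -0.14 and 0.02, so the groups overlapped. The list mean differed by 0.17 in the low-signal and 0.13 in the high-signal arrays, with a camera adjusted p of 0.00136 with the split as a block. Within the high-signal arrays alone the call was lost (adjusted p = 0.0697). Oxidative phosphorylation genes were higher in 26 of 33, with a median of 0.09 (camera adjusted p = 0.00188, and 0.678 with an estimated correlation). Their difference was 0.08 and 0.02 in the low-signal and high-signal arrays, and the call was lost with the split as a block (adjusted p = 0.0592), after quantile normalization (0.721), without HFD-inulin array 1 (0.655) and without HFD array 2 (0.128). Ndufa2 (0.37), Uqcrc2 (0.15), Tfam (0.14) and Ndufs3 (0.15) had the smallest p.

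Acute phase proteins, secreted by hepatocytes in inflammation, and genes of fatty acid oxidation were high in HFD-inulin arrays 1 and 2 and not in array 3. All 21 acute phase genes had higher means in HFD-inulin, with a median of 0.45, and in 0 of them were the groups apart. The camera adjusted p was 0.000163, and 0.638 with an estimated correlation. The list mean was 0.69, 1.77 and -0.17 in HFD-inulin arrays 1 to 3, and 1 HFD array reached 0.27. Saa2 (2.99, SE 1.24), Hp (0.50), Saa1 (2.59) and Apcs (1.80) had the smallest p. Saa2 measured 10.4, 11.3 and 6.25 in HFD-inulin arrays 1 to 3, against 6.34 ± 0.57 (SD, n = 3) in HFD. The difference was 1.24 in the low-signal and -0.17 in the high-signal arrays (adjusted p = 0.00339 with the split as a block). Within the high-signal arrays the list was called lower (adjusted p = 0.0139), and without HFD-inulin array 2 the call was lost (adjusted p = 0.712).

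The fatty acid oxidation and ketogenesis list had 21 of 27 members higher, with a median of 0.39 (camera adjusted p = 0.000397, and 0.638 with an estimated correlation). Its mean was 0.86, 0.62 and -0.15 in HFD-inulin arrays 1 to 3. Acaa2 (0.32), the acyl-CoA thioesterase gene Acot3 (0.89) and Acadvl (0.42) were higher among the members with the smallest p, and Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, was lower (-0.35). The difference was 0.70 in the low-signal and -0.13 in the high-signal arrays (adjusted p = 0.00534 with the split as a block). Within the high-signal arrays this list too was called lower (adjusted p = 0.00230), and without HFD-inulin array 1 the call was lost (adjusted p = 0.0748). Heat shock genes followed the same arrays, at 0.72, 0.50 and -0.08, with 8 of 12 higher and a median of 0.44 (camera adjusted p = 0.0168, and 0.638 with an estimated correlation). Hspe1 (0.71), Hspd1 (0.55), Hsp90aa1 (1.03) and Chordc1 (0.57) had the smallest p. Their difference was 0.56 and -0.05 in the low-signal and high-signal arrays (0.0395 with the split as a block). That call was lost without HFD-inulin array 1 (0.153), HFD-inulin array 2 (0.0672) or HFD array 3 (0.0763). Measured with the same arrays, the neutrophil marker mean was 0.31 above HFD in HFD-inulin array 2 and 0.00 and 0.01 in arrays 1 and 3.

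**Figure D3:**
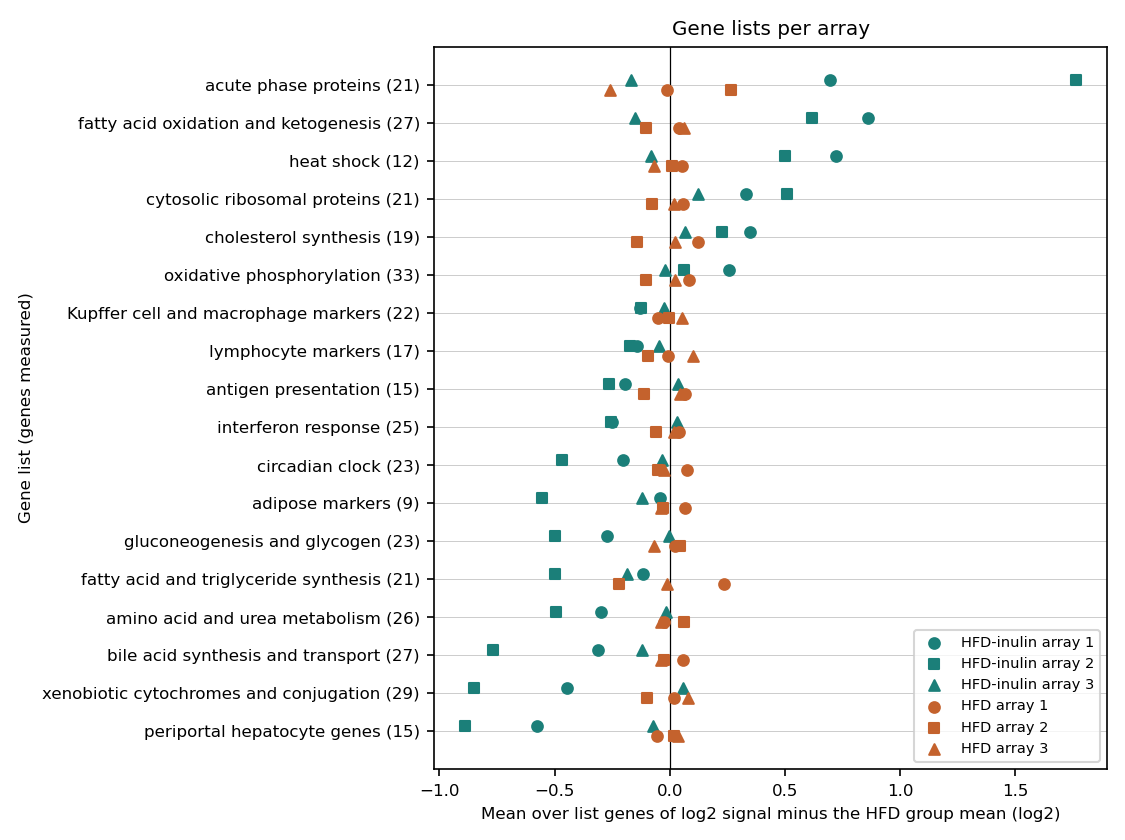
Mean over list genes of the log2 signal minus the HFD group mean, per array, for the 18 lists called by camera; the number of measured genes is in parentheses, HFD-inulin arrays are green, HFD arrays orange, and circle, square and triangle mark arrays 1, 2 and 3. HFD-inulin array 3 lies close to the HFD arrays in most lists, and for cytosolic ribosomal proteins it lies above all 3 of them (0.12 against at most 0.06). It lies below all 3, in the direction of the call, for bile acid (-0.12), adipose (-0.12) and periportal genes (-0.07). For fatty acid oxidation (-0.15) and heat shock genes (-0.08) it lies below all 3, against the call.

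The lists that were lower included several of hepatocyte metabolism. Periportal hepatocyte genes were lower in 12 of 15, with a median of -0.46 (camera adjusted p = 0.000397, and 0.581 with an estimated correlation). Their list mean was -0.58, -0.89 and -0.07 in HFD-inulin arrays 1 to 3, with a difference of -0.68 in the low-signal and -0.10 in the high-signal arrays (0.000939 with the split as a block). Pck1 (-0.65), Cps1, the first enzyme of the urea cycle (-0.68), the histidine ammonia-lyase gene Hal (-1.08) and Uroc1 (-0.83) had the smallest p. Pericentral genes, of the opposite zone of the lobule, had a median of -0.02 over 15 genes and were not called (0.984). The difference between the zones was not tested. Amino acid and urea metabolism genes were lower in 22 of 26, with a median of -0.23 (0.000751, and 0.581 with an estimated correlation). Cps1 and Hal are in this list too, with Got1 (-0.97) and Agxt (-0.45), and its difference was -0.37 and -0.03 in the low-signal and high-signal arrays (0.00339 with the split as a block).

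Xenobiotic cytochromes and conjugation enzymes were lower in 26 of 29, with a median of -0.36 (camera adjusted p = 0.000116, and 0.581 with an estimated correlation). The sulfotransferase gene Sult5a1 (-0.45), the aryl hydrocarbon receptor gene Ahr (-0.66) and Cyp2c38 (a 0.499-fold ratio) were lower, and Arnt, the partner of that receptor, was higher (0.22). The list mean was -0.44, -0.85 and 0.06 in HFD-inulin arrays 1 to 3, with a difference of -0.66 in the low-signal and 0.07 in the high-signal arrays (0.00179 with the split as a block). Bile acid synthesis and transport genes were lower in 19 of 27, with a median of -0.17 (0.00573, and 0.581 with an estimated correlation). The transporter genes Slco1a4 (-2.86, SE 0.93) and Abcb11, the bile salt export pump (-0.60), the conjugating enzyme gene Baat (-0.31) and the nuclear receptor gene Nr0b2 (-0.35) had the smallest p. The difference was -0.60 and -0.09 in the low-signal and high-signal arrays (0.00534 with the split as a block).

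Gluconeogenesis and glycogen genes were lower in 18 of 23, with a median of -0.18 (camera adjusted p = 0.00573, and 0.581 with an estimated correlation). The forkhead factor gene Foxo1 (-0.36), the glycogen-targeting subunit gene Ppp1r3c (-1.31), Pck1 (-0.65) and Got1 (-0.97) had the smallest p. The difference was -0.41 in the low-signal and 0.01 in the high-signal arrays (0.00868 with the split as a block), and without HFD-inulin array 2 the call was lost (0.130). Fatty acid and triglyceride synthesis genes were lower in 14 of 21, with a median of -0.11 (0.0245, and 0.648 with an estimated correlation). Elovl5 (-0.68), Lpin1 (-1.72), the desaturase genes Fads2 (-0.92) and Scd1 (-0.81) had the smallest p. The difference was -0.54 and -0.07 in the low-signal and high-signal arrays (0.00707 with the split as a block). Without HFD-inulin array 2 (0.208), HFD-inulin array 3 (0.0746) or HFD array 1 (0.404) that call was lost, as it was with array weights (0.163) and on ranks (0.0650). Circadian clock genes were lower in 18 of 23, with a median of -0.09 (0.000967, and 0.581 with an estimated correlation). Nr1d1 (-1.06), Ciart (-1.09), Hlf (-0.23) and Bhlhe41 (-0.28) had the smallest p, and the difference was -0.41 in the low-signal and 0.00 in the high-signal arrays (0.00339 with the split as a block).

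Antigen presentation genes were lower in 15 of 15, with a median of -0.13 (camera adjusted p = 0.000951, and 0.634 with an estimated correlation), among them H2-Q4 (-0.24), Tapbp (-0.17), H2-K1 (-0.20) and H2-D1 (-0.12). Interferon response genes were lower in 21 of 25, with a median of -0.12 (0.000967, and 0.581 with an estimated correlation). Rsad2 (-0.70), Oasl1 (-0.20) and Ifit1 (-0.76) were lower, and Zbp1 was higher (0.43). The 2 lists differed by -0.29 and -0.29 in the low-signal and by 0.07 and 0.05 in the high-signal arrays (0.00534 and 0.00707 with the split as a block). Kupffer cell and macrophage markers were lower in 16 of 22, with a median of -0.10 (0.0130, and 0.581 with an estimated correlation), led by Adgre1 (-0.32), Timd4 (-0.32), Folr2 (-0.28) and C1qa (-0.14). Their difference was -0.08 and -0.05 in the low-signal and high-signal arrays (0.0395 with the split as a block), and the call was lost without HFD-inulin array 1 (0.0728) or HFD array 3 (0.0763).

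Lymphocyte markers were lower in 14 of 17, with a median of -0.07 (camera adjusted p = 0.0272, and 0.601 with an estimated correlation), among them Ighm (-1.02), Nkg7 (-0.15), Jchain (-0.23) and Ms4a1 (-0.13). The difference was -0.15 and -0.05 in the low-signal and high-signal arrays, and the call was lost with the split as a block (0.0592), after quantile normalization (0.0729), and without HFD-inulin array 2 (0.203), HFD array 1 (0.0640) or HFD array 3 (0.158). Adipose markers were lower in 7 of 9, with a median of -0.07 (0.0467, and 0.581 with an estimated correlation). Their leading members Pck1 (-0.65) and Car3 (-1.64) are also expressed by hepatocytes, and Ucp1 (-0.13) and Acvr1c (-0.11) lie below the median probe set. The difference was -0.36 and -0.08 in the low-signal and high-signal arrays (0.0395 with the split as a block). The adipose call was lost without HFD-inulin array 3 (0.107), HFD array 1 (0.106), HFD array 2 (0.0918) or HFD array 3 (0.0507). It was also lost after quantile normalization (0.0729), with array weights (0.0559), on ranks (0.0507) and with the replicate number as a block (0.0852).

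The other 21 lists were not called by camera. The unfolded protein response had a median of 0.20 (adjusted p = 0.0513), with a list mean of 0.82 in HFD-inulin array 2. Hepatocyte markers had -0.10 (0.0609), endothelial markers -0.07 (0.0821, and 0.0183 with the split as a block, a call), cholangiocyte markers 0.05 (0.0954), oxidative stress defence 0.11 (0.106), one-carbon metabolism -0.05 (0.122), and lipid droplets and fatty acid uptake 0.22 (0.124). Female-biased liver genes had a median of -0.11 (0.135) and male-biased ones 0.06 (0.269), where the mean was -0.22. Lipoproteins had -0.12 (0.212), glycolysis and fructose metabolism -0.06 (0.252), insulin signalling 0.00 (0.404), neutrophil markers 0.00 (0.424), proliferation -0.03 (0.424) and inflammation 0.01 (0.602). Erythroid markers had -0.03 (0.635), fibrosis and stellate cell markers 0.00 (0.683), immediate early genes -0.02 (0.683), and exocrine pancreas and gut markers 0.03 (0.898). Quantile normalization gave a call, in the same direction, to hepatocyte markers (0.000721), lipoproteins (0.00442), glycolysis and fructose metabolism (0.00972), one-carbon metabolism (0.0124), endothelial markers (0.0147) and male-biased genes (0.0251). Median centring gave one to hepatocyte markers (0.0168), female-biased genes (0.0299) and one-carbon metabolism (0.0477). Leaving out 1 array gave a call to some of the lists. The unfolded protein response was called without HFD-inulin array 1 (0.0141), HFD-inulin array 3 (0.000479) or HFD array 2 (0.0230), and lipid droplet (2.93e-05) and female-biased genes (0.0453) without HFD-inulin array 3. Male-biased genes (0.000317) and cholangiocyte markers (0.0141) were called without HFD-inulin array 1. Endothelial markers were called without HFD-inulin array 1 (0.0423), HFD array 2 (0.0224) or HFD array 3 (0.0337), hepatocyte markers without HFD-inulin array 2 (0.0447) or HFD array 3 (0.0337), and oxidative stress defence without HFD-inulin array 2 (0.00739) or HFD array 1 (0.0329). In the male-biased, insulin signalling, neutrophil, exocrine, noncoding RNA and pericentral lists the median, the mean and the test did not share 1 sign.

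The anchor genes, fixed for their roles in bile acid, lipid and glucose metabolism, gave 0 calls (limma adjusted p from 0.902 to 0.937). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, measured 4.18, 1.31 and 7.18 in HFD-inulin arrays 1 to 3 and 6.43 ± 0.73 (SD, n = 3) in HFD. Its difference of -2.21 had an SE of 1.36, and was -4.50 in the low-signal and 1.15 in the high-signal arrays. Cyp8b1, the sterol 12-alpha-hydroxylase, measured 7.42, 3.33 and 7.42 against 8.28 ± 0.25. The groups did not overlap for 4 of 14 anchor genes, where chance gives 10% if genes are independent, which these need not be. Ppara had a difference of -0.16 (SE 0.07) and Cpt1a -0.35 (SE 0.11), with Pck1 and Cyp8b1 (-2.23, SE 1.07) the others. Scd1 had -0.81, Ppargc1a -0.62 (SE 0.26), Irs1 -0.34, Fgf21 -0.32 and Pparg -0.26. Fasn had 0.44 (SE 0.29), G6pc 0.36, Cd36 0.36 and Irs2 0.35.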

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

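The many-copy split, HFD-inulin array 3 alone and the settings without probe sets that share a profile or are numbered on another chromosome were chosen after seeing the data, and the others before. The count of changed probe sets was 0 without each array in turn (lowest 0, highest 0) and with other normalizations, filters, weights and blocks. It was 4 with a trended and robust prior and 4 at an adjusted p under 0.1, both times 1 profile shared by 4 probe sets. It was 233 at an unadjusted p under 0.05 with a fold of 1.5. For noncoding probe sets it was 0 in each of these, 0 without each array in turn (lowest 0, highest 0), and 5 at the unadjusted p with that fold. Limma's count at an unadjusted p under 0.05 ran from 2100 to 6525 without 1 array, and from 128 to 434 for noncoding probe sets. Called lists numbered 15 to 19 without 1 array, 9 for HFD-inulin array 3 alone and 8 within the high-signal arrays. They numbered 0 with an estimated correlation and 1 with fry. The estimate reached 0.822 for acute phase and 0.786 for ribosomal protein genes, far above the preset 0.01, so the preset adjusted p overstate the evidence for such lists. It was 0.0406 for bile acid genes and -0.107 for adipose markers, which lost their call with the estimate too. Whether correlation accounts for every lost call was not tested. Of the 18 called lists, 13 to 16 kept call and direction without 1 array, 4 with array 3 alone and 2 within the high-signal arrays. With array 3 alone the direction reversed for xenobiotic (adjusted p = 0.478), acute phase (0.00850), fatty acid oxidation (0.000126), antigen presentation (0.721), interferon (0.772), oxidative phosphorylation (0.635), gluconeogenesis (0.992), heat shock (0.155), unfolded protein (7.76e-05) and lipid droplet genes (1.13e-05). Within the high-signal arrays it reversed for xenobiotic, antigen presentation, interferon and heat shock genes (0.595 each), acute phase (0.0139), fatty acid oxidation (0.00230), circadian (0.779), gluconeogenesis (0.765), unfolded protein (0.00342) and lipid droplet genes (0.00132). Both settings lack HFD-inulin arrays 1 and 2 by construction. Of the other values for the 18 called lists, 298 kept direction and call and 81 lost the call. For the lists not called 46 gained it, in 12 lists. Over these alternatives the adjusted p ran from 6.60e-16 to 0.581 for ribosomal proteins, 6.95e-06 to 0.581 for periportal genes, 1.69e-05 to 0.581 for cholesterol synthesis, 1.52e-09 to 0.712 for acute phase, 2.31e-12 to 0.638 for fatty acid oxidation, 5.18e-06 to 0.638 for heat shock and 5.53e-05 to 0.765 for oxidative phosphorylation. It ran from 2.21e-09 to 0.595 for xenobiotic genes, 2.56e-06 to 0.581 for bile acids, 8.07e-08 to 0.775 for amino acids, 1.14e-05 to 0.992 for gluconeogenesis, 1.10e-05 to 0.779 for the clock and 0.000317 to 0.656 for fatty acid synthesis. For antigen presentation it was 4.38e-07 to 0.721, for interferon 3.06e-07 to 0.772, for Kupffer 0.000417 to 0.813, for lymphocyte 0.00640 to 0.635 and for adipose markers 0.0163 to 0.581. Of 631 alternative values of the named genes 9 had another sign, in Cyp7a1, Fasn, Pparg, Cd36 and Fgf21, and 0 passed the threshold. These are anchor genes whose groups overlap. For the 21 genes the rule named outside the anchors, fits on a part of the arrays could not give another sign, because their groups do not overlap. Differences of probe sets with signal near the array median are limited by background.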

Other observations

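The tests in this part were chosen after the results were seen, except those of spermatid genes and of brightness-matched random lists, which were chosen before. Gene families, defined by symbol stems with at least 10 genes, were compared in addition to the fixed lists. Of 164 families camera called 29, and 0 with an estimated correlation (smallest adjusted p 0.835). Of the 29, 20 had a median above 0 and 9 below. Mitochondrial ribosomal proteins of the large subunit (Mrpl) were higher in HFD-inulin in 42 of 46 genes, with a median log2 difference of 0.20 (camera adjusted p = 3.13e-13). In 17 of these proteins' genes the groups did not overlap, where chance gives 10% if genes are independent, which members of a family need not be. Those of the small subunit (Mrps) were higher in 27 of 28, with a median of 0.14 (adjusted p = 2.44e-07), and 3 did not overlap. Mrpl58 measured 5.28 ± 0.15 in HFD-inulin and 4.90 ± 0.04 in HFD (SD, n = 3). Regulatory subunits of the proteasome (Psmd) were higher in 13 of 14, with a median of 0.35 (adjusted p = 5.62e-07), and 5 did not overlap. Mitochondrial import genes (Timm) were higher in 11 of 13, with 0.26 (adjusted p = 1.10e-05), and 8 did not overlap. The family means differed by 0.22 and 0.08 for Mrpl, 0.19 and 0.06 for Mrps, 0.44 and 0.03 for Psmd and 0.20 and 0.11 for Timm in the low-signal and high-signal arrays. Among the lower families, kallikreins (Klk) were lower in 18 of 20, with a median of -0.09 (adjusted p = 0.00395), Kruppel-like factors (Klf) in 12 of 15, with -0.18 (adjusted p = 0.00894), and carboxylesterases (Ces) in 15 of 16, with -0.17 (adjusted p = 0.0124, and 0.1002 with the many-copy split as a block). Sulfotransferases (Sult), lower in 10 of 10 with -0.26 (adjusted p = 0.00201), and cytochromes P450 (Cyp), lower in 54 of 78 with -0.11 (adjusted p = 0.00397), share members with the xenobiotic list. The groups did not overlap in 4 Klk, 3 Klf, 0 Ces, 1 Sult and 13 Cyp genes. The means of Klk, Klf, Ces, Sult and Cyp differed by -0.16, -0.24, -0.43, -0.56 and -0.37 in the low-signal and by -0.02, -0.02, 0.11, 0.08 and -0.04 in the high-signal arrays. The medians of these families kept their sign after quantile normalization and median centring. The small Klk median shrank to -0.05 under each, while that of Klf was -0.19 and -0.15.

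Single genes, chosen after their values were seen, show how HFD-inulin arrays 1 and 2 differed from array 3, and none passed limma's threshold. The serum amyloid gene Saa1 measured 10.43, 11.32 and 6.54 in HFD-inulin arrays 1 to 3 and 6.84 ± 0.70 (SD, n = 3) in HFD. Lcn2, an acute phase gene that encodes lipocalin 2, measured 7.24, 8.20 and 3.73 against 4.22 ± 0.60. Pdk4, a kinase that inhibits pyruvate dehydrogenase, measured 7.03, 7.80 and 3.24 against 3.60 ± 0.22, and Ehhadh, an enzyme of peroxisomal fatty acid oxidation, 10.96, 10.65 and 8.42 against 8.86 ± 0.09. The lncRNA Gm15441 measured 7.65, 6.64 and 3.77 against 3.98 ± 0.26.

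Chromosome Y and other many-copy probe sets split the 6 arrays across the groups. RNA from testis is argued against by 12 spermatid genes, whose median difference between high-signal and low-signal arrays was 0.0331 (range -0.08 to 0.18). The mother's diet is the same within a group. If the labels are right, it cannot be the whole cause of a signal that varied within both groups. The signal ranged from 1.60 to 3.15 within HFD-inulin and from 1.34 to 3.24 within HFD. This follows from the pattern itself, and the test of the group difference (exact permutation p = 0.9, two-sided, smallest possible 0.1) adds nothing to it. A swap of HFD-inulin array 3 with HFD array 1 would make the split the same as the groups. Such a swap stays open below, so the diet is not excluded. Genomic DNA in the labelled material may contribute, since dim many-copy probe sets off chromosome Y exceeded dim unique ones by 0.290, between the 0.1 that would have excluded it and the 0.5 it was taken to need. That value rests on 79 probe sets with 10 distinct profiles, which keeps the explanation open.

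The acute phase and fatty acid oxidation lists were higher in HFD-inulin arrays 1 and 2 than in array 3. Fasting before collection stays open, since 6 fasting genes had medians of -0.439 and -0.244 in arrays 1 and 2 but went both ways, with 2 of 6 above HFD in each. These medians met the criterion first written for excluding fasting. After they were seen, the rule was revised to ask for a margin of the SD over the genes (0.678 and 1.39), which was not met. Brightness-dependent scaling met the criterion written before. The acute phase median of array 1 lay at percentile 95.71 of matched random lists, within their 95% range. The other 3 medians lay at 99.32 or above, outside it, so scaling may account for that median and not for the whole of those. It may supply a part. In array 2 the random lists had a median of 0.188 against 0.518 for fatty acid oxidation, and 0.158 against 1.03 for acute phase. Random genes were drawn by brightness alone, while members of each list moved together, so the percentiles overstate the evidence. A swap of array 3 with an HFD array stays open. It was taken to need an HFD array past the midpoint in both lists, and the largest share of the gap reached in both was 0.0821. The criterion first written for excluding it needed all HFD arrays below the midpoint in both lists. HFD array 2 reached 0.506 in acute phase genes against array 1, and at most 0.0655 in fatty acid oxidation. A looser rule, by which 1 list suffices, was set after the values were seen. Both rules assume that every HFD-inulin liver has these shifts, so they cannot exclude a swap. HFD array 1 correlated more closely with HFD-inulin arrays 1 and 2 (0.9913 and 0.9889) than with HFD arrays 2 and 3, as a swap with array 3 would give. A wrong label from outside these arrays was not tested. White blood cells stay open for array 2, where the neutrophil mean was 0.312 above HFD, while Kupffer and lymphocyte means were below HFD in both arrays, and litter and mother were not tested.

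Cytosolic ribosomal protein genes were higher in HFD-inulin. Brightness-dependent scaling as the whole cause is argued against by a median at percentile 99.98 of matched random lists (95% of these between -0.04 and 0.17). Those lists were drawn by brightness alone, while ribosomal genes moved together, so the percentile overstates the evidence. With the many-copy split as a block 0.806 of the median stayed (0.30 before and 0.24 after), more than genomic DNA was taken to leave. The cause of the split is not known, so this cannot decide on genomic DNA, which stays open. That HFD-inulin arrays 1 and 2 alone carry the difference may still hold, since array 3 lay above the highest HFD array by 0.0664, or 0.944 SD of the HFD arrays. The median of array 3 lay at percentile 99.94 of matched random lists and camera called the list higher with array 3 alone (adjusted p = 7.19e-05), but both rest on 1 array and treat genes as nearly independent, so they do not settle it. The mother's inulin was not tested as a cause and stays open.

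The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. For changed probe sets the real count was 0, which any split reaches (10 of 10), so the comparison says nothing about chance. The highest other was 2149, from the split by many-copy signal. That split was defined on these same arrays and matches the first principal component, so its large count is no separate support. A swap of HFD-inulin array 3 with HFD array 1 would turn it into the group comparison. With that split as a block the count for the diet groups was 0. The same holds for noncoding probe sets (real 0, reached by 10 of 10), with a highest other of 166. For called lists 2 splits, the real one included, gave as many as the real 18, with a highest other of 19, from HFD-inulin arrays 1 and 2 with HFD array 2 against the rest. At an unadjusted p under 0.05 with a fold of 1.5, 4 splits, the real one included, gave as many as the real 233, with a highest other of 2083, again from the split by many-copy signal.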
